A study of Homo sapiens with 12 samples.

How the data were processed

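The authors deposited a table with 34,912 gene and 164,776 transcript entries, in which each library's cell held 3 numbers that no label named. In the deposited values, the first number was read as an estimated count: it was fractional for many genes, its sum differed between libraries, and gene entries equalled the sum of their transcript entries. The second was read as TPM, since it summed to 1,000,000 in every library. The scale of the other number stayed unknown. Per the submitters' processing notes, reads were checked with FastQC, trimmed with Trimmomatic and quantified with kallisto against GRCh38; no versions were given. Per the labels, cells were PC3, the vehicle was 96% ethanol with DMSO, and libraries were made after mRNA enrichment with a directional kit. The estimated counts were analysed, TPM served an alternative, and the remaining number was not used.

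Estimated counts were rounded to whole numbers. The edgeR test planned for estimated counts was not used, because no label named the unit of the deposited cells. The values as read here did not force this choice. In its place, limma-voom was used for every comparison. Analysis ran in R 4.3.3 with limma 3.58.1, and tables and figures in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Library sizes were scaled by TMM factors, computed by own code, and ranged from 0.981 to 1.01. Genes were kept with at least 10 counts, scaled to the median library, in as many libraries as the smallest group, and 15 counts in all, which left 13,722 genes and, in the transcript analysis, 46,726 transcripts. All 12 libraries entered 1 model with 8 residual degrees of freedom (prior 7.65). A contrast was fitted for each compound against vehicle, for each pair of compounds and for the mean of the compounds, and an F-test with 3 coefficients for any compound. P-values were adjusted by Benjamini-Hochberg and called under 0.05. Values per gene are CPM over the scaled library size, given as mean ± SD; fold changes and their 95% CI came from the model. For single shares, exact permutation of the 6 libraries was used. For a group at 0, the mean of the other group was divided by a floor of 3 counts per library.

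Of 38 gene lists written by hand, 34 had 5 or more tested members. They were tested with camera at its preset correlation of 0.01 on log2 CPM (prior count 2), and also with the correlation estimated from the data and with fry, adjusted over the 34 lists. The genes named in the text are the 10 higher and 10 lower with the smallest p among called genes that have a symbol, filled up to 5 per direction from genes with a mean of at least 1 CPM that did not pass, 5 per direction for differences between compounds, a fixed panel of receptors and estrogen targets, and 2 to 4 members of each list that passed. Further called genes are named outside this rule because they passed, among them the mitochondrial genes and their nuclear copies beyond the first 10. Results for 1 panel gene and 2 related lists are not reported here. The comparisons, lists, naming rule and first set of alternatives were fixed before the data were examined; 7 further settings were added after values were seen. Gene identifiers were matched to current symbols for 34,706 genes, and positions were taken from GENCODE 29 on GRCh38.

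Alternatives changed 1 choice at a time: RLE factors, no expression filter, 1 CPM in 3 libraries, a replicate block, only the 2 groups compared, transcripts in place of genes, counts scaled from TPM by length, and leaving out each library. Those added later were sample quality weights, limma-trend, removal of each library's trend on transcript length, GC content or both (splines with 4 degrees of freedom), mitochondrial genes outside the library sizes, and leaving out vehicle replicate 1 with PPT replicate 2. Counts of alternatives given for single genes leave out the analysis of transcripts. Correlations of fold changes were set beside 30 simulations of unchanged groups against shared controls. Sharing of sequence was measured as the part of a gene's 31-base words that occur in another gene.

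Depth was uneven. Vehicle library 1 held 3,238,918 estimated counts and the others 12,410,684 to 15,990,626. No 2 libraries held identical values, and the closest pair of one group (DPN 2 and 3) differed by more than sampling noise (chi-square per degree of freedom 1.57). The analysis was tested on simulated data with 200 changed genes: 1.25-, 1.5- and 2-fold changes were recovered in 50.7, 80.6 and 90.9% with E2, 61.2, 77.6 and 89.4% with PPT, and 59.7, 83.6 and 90.9% with DPN, with 10, 9 and 4 unchanged genes called. When trends with transcript length were simulated, 11.9, 52.2 and 81.8% of 1.25-, 1.5- and 2-fold changes were recovered with PPT when the trends were left in, as in the main analysis, and 53.7, 82.1 and 90.9% when they were removed.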

Results

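The deposited data covered the human prostate cancer line PC3. Cells were kept for 48 h without steroids in medium with 5% charcoal-stripped serum and then received vehicle, 17β-estradiol (E2, 10 nM), the estrogen receptor alpha agonist PPT (1 nM) or the estrogen receptor beta agonist DPN (4.25 nM) for 1 day. Each group held 3 mRNA libraries, 12 in all. The vehicle libraries held 3,238,918, 14,555,479 and 13,441,599 estimated counts, and the E2 libraries 14,039,893, 12,806,158 and 15,990,626. The PPT libraries held 14,964,985, 14,218,806 and 14,170,012, and the DPN libraries 13,672,472, 13,367,243 and 12,410,684. Vehicle library 1 was therefore much shallower than the others. Of 34,912 annotated genes, 13,722 had enough counts to be tested. No source said that the replicates were separate cultures, so the p-values measured only the spread between these libraries, which may be technical. In the deposited labels the compound libraries carried sequencing sample numbers and the vehicle libraries did not, and no label says whether both were sequenced in the same run. The dose differed between the compounds, and each was used at 1 dose only.

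Transcripts of the estrogen receptors were scarce. ESR1 (ENSG00000091831, estrogen receptor alpha, GRCh38 chromosome 6:151656691–152129619) had 3.46 ± 1.70 CPM in vehicle libraries, 4.13 ± 0.559 with E2, 4.57 ± 0.388 with PPT and 3.78 ± 0.483 with DPN (SD, n = 3). ESR2 (ENSG00000140009, estrogen receptor beta, chromosome 14:64084232–64338112) lay lower, at 0.463 ± 0.566, 0.462 ± 0.210, 0.488 ± 0.0554 and 0.758 ± 0.174 CPM. The membrane receptor GPER1 (ENSG00000164850) had 4.69 ± 2.10 CPM in vehicle libraries, and the glucocorticoid receptor NR3C1 (ENSG00000113580) 42.8 ± 1.51 CPM. PGR (progesterone receptor) and the estrogen target GREB1 were too scarce to be tested, with means over the 12 libraries of 0.00563 and 0.435 CPM. Counts of the receptors were low: ESR1 had 5 to 74 and ESR2 0 to 16 estimated counts per library.

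PPT raised the transcripts encoded by the mitochondrial genome. All 13 tested mitochondrial genes, which encode subunits of the respiratory chain and of the ATP synthase, were higher than in vehicle libraries. Together they made up 1.82 ± 0.101% of the estimated counts with PPT against 1.07 ± 0.0400% with vehicle (SD, n = 3; p = 0.1, exact permutation, the smallest value that 3 against 3 libraries can give). MT-ND3 (ENSG00000198840, a complex I subunit, mitochondrial positions 10059–10404) went from 140 ± 4.34 to 270 ± 10.3 CPM, 1.93-fold (log2 0.95, 95% CI 0.79 to 1.11), and MT-CO2 (ENSG00000198712, a cytochrome c oxidase subunit, positions 7586–8269) rose 1.92-fold (0.75 to 1.14 in log2). The smallest increase was that of MT-ND6 (ENSG00000198695), the complex I subunit encoded on the other strand, at 1.52-fold. Each PPT library lay above each vehicle library for MT-ND3. The adjusted p was 1.34e-05 for MT-ND3, 6.57e-05 for MT-CO2 and 0.0244 for MT-ND6 (limma-voom). Between 11 and 13 of the 13 genes passed in each alternative analysis of genes. MT-ND5 and MT-ND6 did not pass without vehicle replicate 1, 2 or 3 or PPT replicate 1 (highest adjusted p 0.141 and 0.169). With transcripts tested in place of genes, 1 transcript in all passed with PPT. At most 1 mitochondrial transcript therefore kept its call in that alternative.

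**Figure D1:**
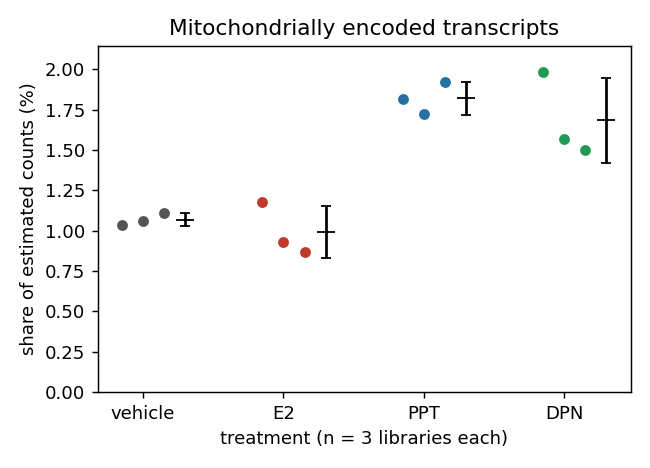
Share of the estimated counts in the 13 mitochondrially encoded genes, 1 point per library, with the mean and SD of each group.

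Entries for nuclear copies of mitochondrial genes went the same way with PPT. MTRNR2L12 (ENSG00000269028, chromosome 3:96617188–96618236), a copy of part of the mitochondrial 16S rRNA, rose 2.17-fold (log2 1.12, 95% CI 0.93 to 1.31; adjusted p = 1.34e-05, limma-voom). The copies MTRNR2L8, MTRNR2L1, MTRNR2L11, MTATP6P1 and MTRNR2L6 also passed. MTRNR2L6 was lost in 11 of 25 alternatives, among them those without any single vehicle library, E2 replicate 2 or 3, PPT replicate 1 or DPN replicate 2 (highest adjusted p 0.395). The part of the 31-base words that also occurred in other genes was 53.4% for MTRNR2L12, 40.7% for MTRNR2L8, 10.7% for MTRNR2L1, 5.45% for MTRNR2L11, 8.68% for MTRNR2L6 and 63.9% for MTATP6P1. The deposited gene types included no mitochondrial rRNA, so the 16S rRNA had no entry of its own. Whether its reads were counted for the MTRNR2L copies was not tested, so these rises need not be those of nuclear transcripts.

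Among other nuclear genes, PPT raised 3 transcripts, named here because they passed and not by the naming rule. COL7A1 (ENSG00000114270, the anchoring fibril collagen, chromosome 3:48564073–48595267) went from 0.290 ± 0.0622 to 1.42 ± 0.177 CPM (4.33-fold, log2 2.11, 95% CI 1.41 to 2.82), from 1, 5 and 3 counts with vehicle to 22, 17 and 22 with PPT. TUBE1 (ENSG00000074935, epsilon-tubulin of the centriole, chromosome 6:112070777–112087529) rose 1.54-fold, from 8.29 ± 0.356 to 12.98 ± 1.11 CPM. C15orf48 (ENSG00000166920, a small protein of the cytochrome c oxidase complex, chromosome 15:45430529–45448761) rose 1.72-fold, from 32.4 ± 5.95 to 54.64 ± 11.04 CPM. For each of the 3 genes, every PPT library was above every vehicle library. In all, PPT raised 22 genes and lowered 0 (limma-voom; 1966 genes had an unadjusted p under 0.05, and limma-trend called 25). The adjusted p was 0.00790 for COL7A1, 0.0371 for TUBE1 and 0.0483 for C15orf48. These calls depended on single libraries: COL7A1 did not pass without vehicle replicate 2 or 3 (highest adjusted p 0.411), TUBE1 was lost in 12 of 25 alternatives, among them those without any single vehicle library, E2 replicate 1, PPT replicate 1 or 2 or DPN replicate 2 or 3 (highest adjusted p 0.395), and C15orf48 in 12 of 25, among them those without vehicle replicate 1 or 3, PPT replicate 1 or any single E2 or DPN library (0.614). The whole count went to 1835 genes without PPT replicate 3, of which 940 were higher and 895 lower, and to 1 when transcripts were tested.

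Several groups of nuclear genes shifted together with PPT. Ribosomal protein transcripts were higher for 76 of 76 genes, with a median log2 fold change of 0.17 and RPS29 (ENSG00000213741) 1.39-fold higher. The rise was uneven between libraries: ribosomal protein genes held 6.01%, 6.90% and 5.34% of the estimated counts in PPT replicates 1, 2 and 3, against 5.83%, 5.54% and 5.23% in the vehicle libraries, and RPS29 had 156 CPM in PPT replicate 3 against 170 in vehicle replicate 1. PPT replicate 2 also stood apart in transcript length, with a correlation of its deviations with length of −0.570. Without it the ribosomal protein list had camera adjusted p = 0.000808, while over all libraries the list had adjusted p = 0.511 with an estimated correlation. Genes of the integrated stress response, the program that ATF4 drives when translation is restrained, had a median of 0.19 and were higher for 23 of 24 members. Among them, CHAC1 (ENSG00000128965, which degrades glutathione) was 1.60-fold higher, the stress cytokine GDF15 (ENSG00000130513) 1.26-fold and asparagine synthetase ASNS 1.16-fold. Hypoxia and glycolysis genes were higher for 29 of 32 members (median 0.13; ALDOC, aldolase C, 1.27-fold), and nuclear genes of oxidative phosphorylation for 66 of 73 (median 0.14; NDUFB1, a complex I subunit, 1.38-fold). Over all libraries, camera gave adjusted p = 2.02e-13 for ribosomal proteins, but adjusted p = 0.511 with an estimated correlation. The integrated stress response list had adjusted p = 2.42e-09 by camera, adjusted p = 0.359 with an estimated correlation, and 0.0381 by fry. Hypoxia and glycolysis had adjusted p = 2.12e-08 by camera and adjusted p = 0.511 with an estimated correlation. Nuclear oxidative phosphorylation had adjusted p = 2.12e-08 by camera and adjusted p = 0.581 with an estimated correlation, and did not pass without PPT replicate 2 (adjusted p = 0.0922). No member of these 4 lists passed over all genes by limma-voom. Adjusted over the list alone, 9 integrated stress response genes and 7 hypoxia genes passed and 0 ribosomal protein and 0 oxidative phosphorylation genes did (limma-voom). The mitochondrial list itself had adjusted p = 7.79e-25 by camera, adjusted p = 0.359 with an estimated correlation, and 0.00675 by fry.

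**Figure D2:**
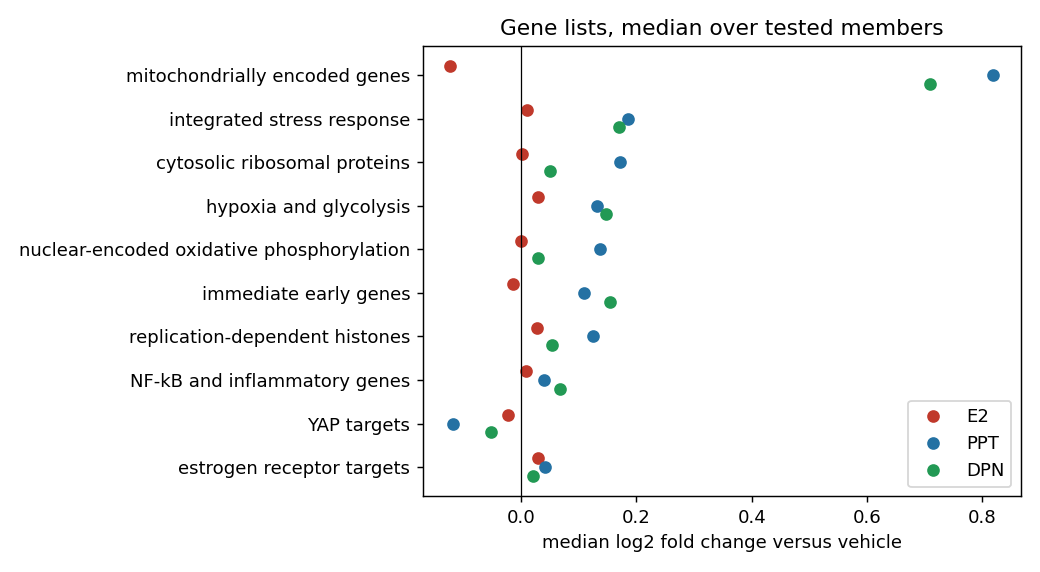
Median log2 fold change of 10 gene lists with E2, PPT and DPN against vehicle.

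Smaller shifts with PPT concerned inflammatory, growth-related and histone genes. The chemokine genes CXCL2 and CXCL8, members of the NF-kB list, were 1.33-fold and 1.38-fold higher, and 5 of the list's 32 genes passed when adjusted over the list alone (camera adjusted p = 0.0119, adjusted p = 0.511 with an estimated correlation). CXCL8 had 1063, 1306 and 807 CPM in PPT replicates 1, 2 and 3, against 834, 791 and 657 in the vehicle libraries. Immediate early genes were higher for 17 of 22 members, 1 of which passed when adjusted over the list alone (camera adjusted p = 0.0144, adjusted p = 0.511 with an estimated correlation). YAP targets were lower for 14 of 19 members, among them AXL, CRIM1 and FJX1, with log2 fold changes of −0.19, −0.23 and −0.21, and 3 were lower when adjusted over the list alone (camera adjusted p = 0.0403, adjusted p = 0.511 with an estimated correlation). Replication-dependent histone genes were higher for 10 of 11, with the linker histone HIST1H1C at 1.21-fold and 1 gene past when adjusted over the list alone (camera adjusted p = 0.0446, adjusted p = 0.511 with an estimated correlation). The NF-kB shift did not pass without vehicle replicate 3 or PPT replicate 1 (highest adjusted p 0.108). The immediate early gene shift did not pass without vehicle replicate 1 or PPT replicate 3 (highest adjusted p 0.127). The YAP shift was lost in 7 of 17 alternatives, among them those without vehicle replicate 2 or 3, PPT replicate 2 or DPN replicate 3 (highest adjusted p 0.274), and the histone shift was kept in 6 of 17 and lost, among others, without vehicle replicate 2 or 3, E2 replicate 1 or 2, PPT replicate 1 or 2 or any single DPN library (highest adjusted p 0.413).

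Of the estrogen target genes, none passed over all genes with PPT. TFF1 (ENSG00000160182, a secreted trefoil peptide, chromosome 21:42362282–42366594) was 1.33-fold higher, at 111 ± 11.1 against 84.5 ± 5.42 CPM (log2 0.41, 95% CI 0.23 to 0.60), in 3 of 3 libraries, at adjusted p = 0.110 (limma-voom). It passed with the replicate block (adjusted p = 0.0163), with sample quality weights (0.000292) and without PPT replicate 3 (0.00234). CCND1, MYC, CTSD, NRIP1, SIAH2, STC2 and IGFBP4 had log2 fold changes between −0.14 and 0.08, and of these CCND1 passed without PPT replicate 3 only (adjusted p = 0.0193). The 41 tested estrogen receptor targets had a median of 0.04 (camera adjusted p = 0.495), and 1 was higher and 1 lower when adjusted over the list alone. The zinc exporter gene SLC30A1 and the retinaldehyde dehydrogenase gene ALDH1A3 had the smallest p among lower genes, with log2 fold changes of −0.44 and −0.21, and did not pass (adjusted p = 0.0764 and 0.0724, limma-voom). SLC30A1 passed in 6 of 25 alternatives, among them those without PPT replicate 3 or DPN replicate 1 (lowest adjusted p 0.00118), and ALDH1A3 in 5 of 25, among them those without PPT replicate 2 or 3 (0.000159).

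DPN also raised mitochondrially encoded transcripts. MT-ND3 reached 253 ± 22.8 CPM, 1.81-fold the vehicle level (log2 0.86, 95% CI 0.70 to 1.02), and MT-CO2 rose 1.78-fold (0.64 to 1.03 in log2). The 13 genes had a median log2 fold change of 0.71 and held 1.68 ± 0.263% of the estimated counts against 1.07 ± 0.0400% with vehicle (SD, n = 3; p = 0.1, exact permutation, the smallest possible). The adjusted p was 8.30e-05 for MT-ND3 and 0.000499 for MT-CO2 (limma-voom). Of the 13 genes, 11 passed over all genes, the exceptions being MT-ND5 and MT-ND6. The number depended on single libraries. It was 6 without vehicle replicate 1, 2 without vehicle replicate 2 and 8 without vehicle replicate 3. Without DPN replicate 1 it was 7, and without DPN replicate 2 it was 9. In these fits the median stayed between 0.58 and 0.79. With transcripts tested in place of genes, 1 transcript in all passed with DPN, so at most 1 mitochondrial transcript did.

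Of the other genes, ELF3 (ENSG00000163435, an epithelial ETS transcription factor, chromosome 1:202007945–202017188) rose 1.22-fold with DPN, from 108 ± 3.24 to 131 ± 6.77 CPM (log2 0.28, 95% CI 0.17 to 0.40). COL7A1 rose 3.52-fold, to 1.14 ± 0.119 CPM (log2 1.82, 95% CI 1.09 to 2.54). The histone H4 genes HIST2H4B (ENSG00000270276, chromosome 1:149854045–149861210) and HIST2H4A (ENSG00000270882, chromosome 1:149832659–149839767) moved in opposite directions, to 13.1 ± 1.40 from 6.06 ± 1.83 CPM and to 8.62 ± 1.42 from 16.4 ± 0.702 CPM. The 2 genes shared 97.2% and 98.6% of their 31-base words with other genes, so how reads were divided between them is uncertain. The unnamed gene AD000671.2 (ENSG00000267120, chromosome 19:35739252–35745432) had 0 counts in all DPN libraries and 4, 5 and 13 in the vehicle libraries. Its vehicle mean of 0.843 ± 0.455 CPM was 3.68-fold a floor of 3 counts per library. ELF3, COL7A1 and HIST2H4B are named because they passed, not by the naming rule. DPN raised 18 genes and lowered 2 (limma-voom; 773 genes had an unadjusted p under 0.05, and limma-trend called 20), with adjusted p = 0.0490 for ELF3, COL7A1 and HIST2H4A, 0.0138 for HIST2H4B and 0.0308 for AD000671.2. The count fell to 11 without vehicle replicate 1, 6 without vehicle replicate 2, 12 without vehicle replicate 3, 12 without DPN replicate 1 and 13 without DPN replicate 2, and to 1 when transcripts were tested. COL7A1 was lost when any 1 of the 12 libraries was left out (highest adjusted p 0.669), HIST2H4A without any single vehicle, E2 or DPN library (0.669), and ELF3 without any single vehicle or E2 library, PPT replicate 1 or DPN replicate 1 or 2 (0.701). AD000671.2 did not pass without vehicle replicate 1 or 3, PPT replicate 1 or any single E2 or DPN library (0.433), and HIST2H4B without vehicle replicate 3 or DPN replicate 2 (0.216).

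The stress and hypoxia groups were higher with DPN too. Hypoxia and glycolysis genes were higher for 30 of 32 members, with NDRG1 at 1.33-fold, ALDOC at 1.28-fold and the phosphofructokinase regulator PFKFB4 at 1.22-fold. Integrated stress response genes were higher for 22 of 24, with GDF15 at a log2 fold change of 0.32 and the mTORC1 inhibitor gene DDIT4 at 1.36-fold. Immediate early genes had a median log2 fold change of 0.15, with ATF3 at 1.36-fold and the phosphatase gene DUSP1 at 1.27-fold, and NF-kB genes a median of 0.07. Camera gave adjusted p = 9.49e-14 for hypoxia and glycolysis (adjusted p = 0.263 with an estimated correlation). For the integrated stress response it was 7.42e-11 (adjusted p = 0.247 with an estimated correlation). For immediate early genes it was 0.000620 (adjusted p = 0.346 with an estimated correlation), and for NF-kB genes 0.000961 (adjusted p = 0.401 with an estimated correlation). The mitochondrial list had adjusted p = 2.07e-27 by camera, adjusted p = 0.247 with an estimated correlation, and 0.0206 by fry. Adjusted over the list alone, 9 hypoxia, 10 integrated stress response, 2 immediate early and 0 NF-kB genes passed, and 13 of the 13 mitochondrial genes. The NF-kB shift did not pass without vehicle replicate 3 (adjusted p = 0.140).

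Receptor and target genes showed no change with DPN that passed the test. TFF1 had 92.2 ± 10.4 CPM (log2 0.14, 95% CI −0.04 to 0.33; adjusted p = 0.931, limma-voom), STC2 a log2 fold change of 0.21, SIAH2 of 0.14 and ESR2 of 0.68 (95% CI −0.41 to 1.77). The estrogen receptor target list had a median of 0.02 (camera adjusted p = 0.284). CYP1A1, a cytochrome P450 that hydroxylates estradiol, went from 0.235 CPM with vehicle to 1.14 with DPN and 1.05 with E2 (log2 1.84 and 1.73). It passed only when adjusted over the list alone, within the aryl hydrocarbon receptor and steroid metabolism lists, and not over all genes (adjusted p = 0.236 and 1.00, limma-voom).

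E2 changed no gene past the threshold. The smallest p was that of INPP4B (ENSG00000109452, a phosphatase that removes phosphate from inositol lipids of the PI3K pathway, chromosome 4:142023160–142847432), which was 1.27-fold higher, at 80.0 ± 7.29 against 63.4 ± 2.84 CPM (log2 0.35, 95% CI 0.21 to 0.48), in 3 of 3 libraries. Next came HIST2H4B and HIST2H4A, again in opposite directions (log2 0.94 and −0.73). TFF1 was 1.17-fold higher (log2 0.22, 95% CI 0.04 to 0.41), and the estrogen receptor targets were higher for 29 of 41 members, with a median log2 fold change of 0.03. COL7A1 had a log2 fold change of 1.52 and was higher than every vehicle library in 3 of 3 E2 libraries. Mitochondrially encoded genes were slightly lower for 12 of 13 members (median −0.12), at 0.992 ± 0.163% of the estimated counts (SD, n = 3; p = 0.5, exact permutation). The median was −0.237 without E2 replicate 1 and −0.0340 without E2 replicate 3. E2 replicate 1 held 1.18%, above each vehicle library (1.03% to 1.11%). The count of genes was 0 by limma-voom (1 without PPT replicate 2) and 0 by limma-trend, with 352 genes at an unadjusted p under 0.05. That is fewer than 13,722 unchanged genes would give at that level. All groups shared 1 estimate of the spread, to which the wider PPT libraries contributed. With only E2 and vehicle compared, 431 genes had such a p and 1 was called. With sample quality weights the values were 756 and 0. The adjusted p was 1.00 for INPP4B, TFF1 and COL7A1, and camera gave 0.333 for the estrogen receptor targets and 0.0606 for the mitochondrial genes. With the replicate block the mitochondrial list passed as lower with E2 (camera adjusted p = 0.0322), and without the block it had adjusted p = 0.978 with an estimated correlation. The hypoxia and glycolysis list passed with a median of 0.03 and 28 of 32 members higher (camera adjusted p = 0.0488, adjusted p = 0.978 with an estimated correlation), 0 of them past when adjusted over the list alone. It was lost in 8 of 17 alternatives, among them those without vehicle replicate 1 or 3, E2 replicate 2 or 3, PPT replicate 1 or 3 or DPN replicate 2 (highest adjusted p 0.965). The median half-width of the 95% CI was 0.191 in log2, or 1.14-fold, and in data simulated without trends on transcript length 80.6% of 1.5-fold changes were recovered with E2. With such trends simulated and left in, as in the main analysis, 52.2% were recovered in the comparison of PPT with vehicle. The simulations gave all groups the same spread, unlike the data, so the recovery with E2 is uncertain.

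The compounds differed from each other mainly in mitochondrial transcripts. MT-ND3 was 1.96-fold lower with E2 than with PPT (log2 −0.97, 95% CI −1.12 to −0.82) and 1.83-fold lower than with DPN (log2 −0.87, 95% CI −1.03 to −0.72). All 13 mitochondrial genes were lower with E2 than with PPT and than with DPN, and over all genes 13 passed against PPT and 12 against DPN. The adjusted p for MT-ND3 was 4.44e-06 and 3.24e-05 (limma-voom). The whole list had camera adjusted p = 2.22e-32 against PPT (adjusted p = 0.219 with an estimated correlation). Against DPN it had camera adjusted p = 6.07e-40 (adjusted p = 0.123 with an estimated correlation), and 13 genes passed when adjusted over the list alone in each comparison. Of the 12 genes against DPN, 10 passed without E2 replicate 2 or 3 and 11 without DPN replicate 1 or 2. With transcripts tested in place of genes, 13 transcripts in all passed against PPT and 1 against DPN, each lower with E2. Entries for nuclear copies of mitochondrial genes were also lower with E2, 6 of them against PPT and 5 against DPN. MTRNR2L12 had log2 differences of −1.19 and −0.99 and passed in 25 of 25 alternative analyses of genes in both comparisons. MTRNR2L6 was lost against PPT without E2 replicate 2 or 3 or PPT replicate 1 (highest adjusted p 0.116), and MTRNR2L11 against DPN without any single E2 or DPN library (0.171).

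INPP4B was 1.35-fold higher with E2 than with DPN, at 80.0 ± 7.29 against 59.2 ± 1.96 CPM (log2 0.43, 95% CI 0.30 to 0.56), with each E2 library above each DPN library. With PPT it had 79.2 ± 1.05 CPM. ATF3 (ENSG00000162772, a stress-induced transcription factor, chromosome 1:212565334–212620777) was lower with E2 than with DPN, at 25.9 ± 0.684 against 37.0 ± 4.53 CPM (1.43-fold, log2 −0.51, 95% CI −0.71 to −0.31), and had 36.7 ± 4.25 CPM with PPT. The INPP4B difference passed at adjusted p = 0.00388 (limma-voom), and in 25 of 25 alternative analyses of genes (log2 0.36 to 0.59, adjusted p 0.000351 to 0.0442). With transcripts tested in place of genes, 1 transcript in all passed between E2 and DPN. It was lower with E2, so no INPP4B transcript passed as higher. The ATF3 difference passed at 0.0483 against DPN and not against PPT (0.0524), and was lost in 14 of 25 alternatives, among them those without any single vehicle or E2 library, PPT replicate 1 or DPN replicate 1 or 2 (highest adjusted p 0.303).

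**Figure D3:**
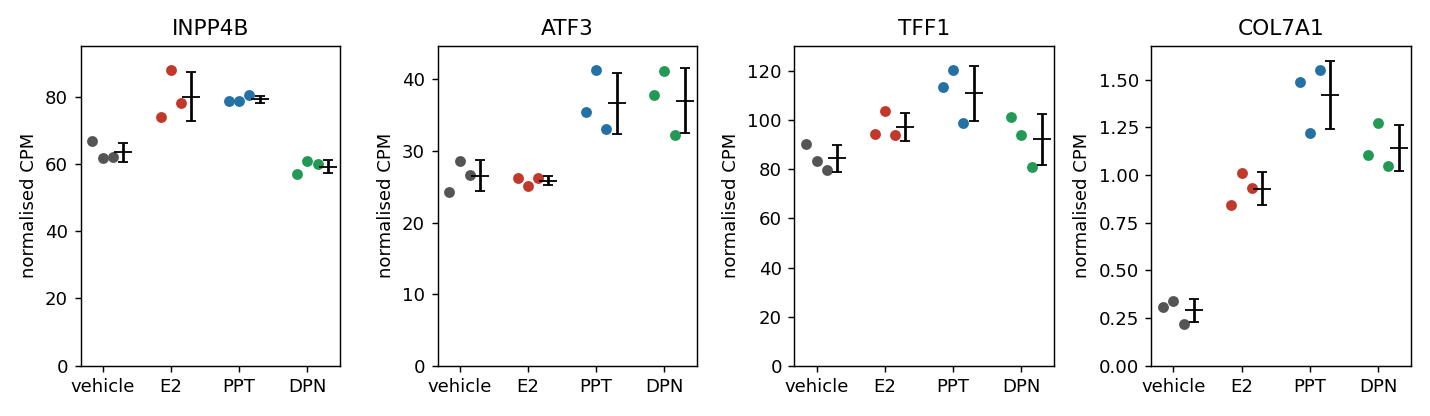
Normalised CPM of INPP4B, ATF3, TFF1 and COL7A1, 1 point per library, with the mean and SD of each group.

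A gene with an overlapping model was called between E2 and PPT and another between E2 and DPN. The readthrough gene MSH5-SAPCD1 (ENSG00000255152, chromosome 6:31740020–31764851) had 3, 0 and 0 counts with E2 and 25, 12 and 23 with DPN (adjusted p = 0.0136, limma-voom). AC005832.4 (ENSG00000272921, chromosome 12:4604944–4662643) had 0 counts in all E2 libraries and 47, 12 and 29 with PPT (adjusted p = 0.0368, limma-voom). Its PPT mean of 2.03 ± 1.16 CPM was 9.64-fold a floor of 3 counts per library. Between 87.8% and 96.4% of the 31-base words of AD000671.2, AC005832.4 and MSH5-SAPCD1 occurred in other genes, so these values depend on how reads were divided. In all, 20 genes were lower and 0 higher with E2 than with PPT (1777 at an unadjusted p under 0.05; limma-trend 19). Against DPN, 1 gene was higher and 19 were lower (810 at an unadjusted p under 0.05; limma-trend 19). PPT and DPN differed in 0 genes by limma-voom and 0 by limma-trend, with 1282 at an unadjusted p under 0.05. MSH5-SAPCD1 did not pass without E2 replicate 2 or 3 or DPN replicate 1 or 3 (highest adjusted p 0.298), and AC005832.4 did not pass without vehicle replicate 2 or 3, PPT replicate 1 or any single E2 or DPN library (0.427). Without PPT replicate 3 the counts were 1629 between E2 and PPT (776 higher and 853 lower with E2) and 1348 between PPT and DPN (634 higher and 714 lower with PPT), where 3 genes were called without PPT replicate 2 and 1 without vehicle replicate 1, E2 replicate 1 or 2 or DPN replicate 1.

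Several gene lists differed between the compounds by camera, and none with an estimated correlation. Against PPT, E2 had lower ribosomal proteins (median −0.17; camera adjusted p = 3.70e-17), nuclear oxidative phosphorylation (−0.14; 1.86e-11), integrated stress response (−0.12; 2.11e-08), hypoxia (−0.10; 8.20e-05), immediate early (−0.11; 0.0124), NF-kB (−0.04; 0.0132) and histone genes (−0.12; 0.0435). YAP targets (0.09; 0.0414) and estrogen receptor coregulators (0.10; 0.0435) were higher. All of these had adjusted p = 0.588 with an estimated correlation, except the integrated stress response (adjusted p = 0.566 with an estimated correlation). Against DPN, E2 had lower integrated stress response (−0.10; camera adjusted p = 5.96e-10), hypoxia (−0.10; 2.69e-09), immediate early (−0.12; 0.000373), NF-kB (−0.08; 0.00141) and ribosomal protein genes (−0.05; 0.0489). Their values were adjusted p = 0.303, 0.380, 0.369, 0.393 and 0.850 with an estimated correlation. PPT had higher ribosomal protein (0.13; camera adjusted p = 5.52e-12), nuclear oxidative phosphorylation (0.11; 5.86e-09), histone (0.12; 0.0284) and mitochondrial genes (0.14; 0.0189) than DPN. The mitochondrial median fell to 0.0188 after length and GC trends were removed. It was 0.0460 without DPN replicate 3 and 0.262 without DPN replicate 1. The ribosomal protein share of the counts was 5.34% in PPT replicate 3, below each DPN library (5.54% to 5.68%) and each E2 library (5.43% to 5.65%), and 6.90% in PPT replicate 2. Genes of the TGF-beta and mesenchymal list (−0.12; 0.0181) and coregulators (−0.09; 0.0487) were lower. These 6 lists, mitochondrial genes included, had adjusted p = 0.770 with an estimated correlation. Against vehicle, camera had not called coregulators with PPT (adjusted p = 0.148) or ribosomal proteins with DPN (adjusted p = 0.191). With vehicle replicate 1 and PPT replicate 2 both left out, ribosomal proteins passed as higher with DPN (camera adjusted p = 3.10e-08) and E2 (0.0415), and nuclear oxidative phosphorylation as higher with DPN (0.000170). With all libraries these had adjusted p = 0.996, 0.978 and 0.996 with an estimated correlation.

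PPT and DPN shared 16 of their 22 and 18 higher genes. Independent calls would share 0.0289, and simulated unchanged groups with shared controls shared at most 0. Neither value can test the overlap. The mitochondrial genes and their copies moved together, while the simulations drew genes separately and with none changed. The 16 shared genes were the 11 mitochondrial genes of the DPN set, their nuclear copies and COL7A1. The mean of the 3 compounds differed from vehicle in 4 genes, all higher: MT-ND3, MT-CO2, MTRNR2L12 and MTRNR2L8 (limma-voom; 770 genes at an unadjusted p under 0.05; limma-trend 13). None of these 4 genes had a higher mean with E2 than with vehicle. Mean CPM with E2 and vehicle was 139 and 140 for MT-ND3 and 974 and 1057 for MT-CO2. It was 892 and 926 for MTRNR2L12 and 79.4 and 82.3 for MTRNR2L8. The 4 calls thus came from PPT and DPN and do not show a response common to the 3 compounds. MT-CO2 and MTRNR2L8 did not pass without vehicle replicate 1, 2 or 3 (highest adjusted p 0.107 and 0.170). The count was 2 without vehicle replicate 2 or 3, 7 without E2 replicate 1, 12 without E2 replicate 3, 17 without PPT replicate 2, 19 without PPT replicate 3 and 8 without DPN replicate 1. The genes changed by any compound numbered 24 (limma-voom, 3 coefficients; 980 at an unadjusted p under 0.05), with INPP4B among them (adjusted p = 0.00393), and 663 without PPT replicate 3. For the mean of the compounds, camera gave adjusted p = 1.41e-21 for mitochondrial genes (adjusted p = 0.336 with an estimated correlation). Hypoxia genes had 4.37e-11 (adjusted p = 0.402 with an estimated correlation), integrated stress response genes 2.68e-09 (adjusted p = 0.336 with an estimated correlation) and ribosomal proteins 0.000157 (adjusted p = 0.763 with an estimated correlation). NF-kB genes had 0.00602 and immediate early genes 0.0106 (adjusted p = 0.508 with an estimated correlation for both), and oxidative phosphorylation genes 0.0207 (adjusted p = 0.834 with an estimated correlation).

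Fold changes against the shared vehicle libraries were compared across the 13,722 genes with 30 simulations of unchanged groups. Pearson r was 0.532 for E2 and PPT, below all simulations (0.556 to 0.614). It was 0.556 for E2 and DPN and 0.580 for PPT and DPN, inside the simulated ranges (0.536 to 0.611 and 0.554 to 0.600). The jackknife SD of r was 0.212, 0.213 and 0.206 for the 3 pairs. That is wider than any of the simulated ranges, so the place of r against them is uncertain. The covariances of 0.0344, 0.0340 and 0.0393 lay above all simulations (highest 0.0174, 0.0174 and 0.0171) and exceeded the simulated means by 0.0185, 0.0180 and 0.0232. The simulations drew counts with the median spread of genes of like expression and without trends between libraries. Real libraries that vary more would raise the covariance with no shared response. With 3 vehicle libraries the controls could not be parted into 2 sets of at least 2 libraries. All of this excess may therefore come from the shared controls, and the covariances cannot test a shared response.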

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

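The tests of the mitochondrial pattern, of the histone H4 pair and of the depth of PPT replicate 2 were chosen only after the result was seen; the test of length and GC trends among the PPT libraries was not.

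A closer look was called for where the difference between 2 compounds itself passed the test. MT-ND3 differed between E2 and PPT (log2 −0.97) and between E2 and DPN (log2 −0.87). INPP4B (0.43) and ATF3 (−0.51) differed between E2 and DPN. The overlapping genes AC005832.4 (E2 against PPT, −5.72 as fitted) and MSH5-SAPCD1 (E2 against DPN, −4.48) had 0 to 3 counts per library with E2. Their fitted values therefore depend on the prior count. For AC005832.4 the PPT mean was 9.64-fold the floor. The compounds were given at different doses, so dose could not be told apart from the compound. No role of a receptor in these differences was tested. For INPP4B the difference ranged from 0.36 to 0.59 over the alternative analyses of genes.

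The mitochondrially encoded transcripts were higher with PPT and DPN and not with E2. After trends on transcript length and GC content were removed, the lower of the 2 medians was still 0.718 in log2, against 0.82 with PPT and 0.71 with DPN before. Nuclear genes of oxidative phosphorylation had medians of 0.136 with PPT and 0.0284 with DPN, so a like rise of all respiratory chain transcripts is argued against. Without the shallow vehicle replicate 1, 11 of the 13 genes still passed with PPT, and 6 of 13 with DPN, where the median stayed at 0.674 and calls were also lost without vehicle replicate 2 (2 of 13 passed) or 3 (8 of 13). The labels of the compound libraries carry sequencing sample numbers and those of the vehicle libraries do not; a separate run of the vehicle libraries would move the compounds alike, and the median with E2 was −0.124, so it is argued against for this rise and stays open for other differences from vehicle. Differences in RNA quality or in the handling of the plates were not tested, and any that followed the groups could not be told apart from the compounds.

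The PPT libraries spread more than those of the other groups. PPT replicate 3 lay closer to the DPN libraries (chi-square per degree of freedom 2.22 to 2.57) than to PPT replicates 1 and 2 (7.63 and 16.5). Against the vehicle libraries it had 3.75 to 5.39. PPT replicates 1 and 2 also differed from each other (8.39). From the DPN libraries they differed by 6.27 to 7.03 and by 12.8 to 13.7. These values do not single out PPT replicate 3 as the deviating library, and the cause of the spread was not settled. Comparisons of PPT with DPN depend on whether PPT replicate 3 is included. Without PPT replicate 3 the comparison with vehicle called 1835 genes; after trends on transcript length and GC content were removed it called 703, between the 2 bounds set beforehand, so these trends may account for part of the spread, and the test was left undecided. Correlations of each library's deviations with transcript length were −0.379, −0.570 and 0.326 for PPT replicates 1, 2 and 3. Depth is argued against, since PPT replicate 2 held 14,218,806 estimated counts, inside the range of the other compound libraries. No biological explanation was tested.

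HIST2H4A and HIST2H4B moved in opposite directions with DPN. The summed counts of both genes changed by −0.0452 in log2, under the bound of 0.2, as would be seen if reads were divided differently between 2 near-identical genes. A candidate explanation is therefore the assignment of reads, and a real exchange of expression between the copies stays open.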

How the results depend on the processing

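Sample quality weights, limma-trend, the removal of length and GC trends, mitochondrial genes outside the library sizes and the fit without both doubted libraries were chosen only after the result was seen; the other settings were planned. The planned edgeR test and its DESeq2 alternative were not run, because no label named the unit of the cells. Read as estimated counts, the values would have allowed a count model, so what it would call is unknown.

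Counts of called genes depended on how the libraries were weighed and on which were left out. With sample quality weights, which gave PPT replicate 1 a weight of 6.08 and PPT replicates 2 and 3 weights of 0.303 and 0.369, 2177 genes were called with PPT (1071 higher and 1106 lower; 22 without weights, all higher), 36 with DPN (20), 27 for the mean of the compounds (4), 2487 between E2 and PPT (1242 higher and 1245 lower with E2; 20 without weights, all lower), 46 between E2 and DPN (20), and 1840 between PPT and DPN (0), and the genes changed by any compound numbered 1390 (24). With transcripts in place of genes the counts were 1 with PPT, 1 with DPN, 13 between E2 and PPT and 1 between E2 and DPN, and 4 genes were changed by any compound; for the mean of the compounds 6 transcripts were called, all lower, where the 4 genes had all been higher. With only the 2 groups compared they were 1 with E2, 60 between E2 and DPN and 2 between PPT and DPN. Counts scaled from TPM by length gave 13 with DPN. For the mean of the compounds, RLE size factors gave 8, no expression filter 13, at least 1 CPM in 3 libraries 9, limma-trend 13 and removal of the length trend 10. Between PPT and DPN, removal of length and GC trends gave 2 and of the length trend alone 1. With vehicle replicate 1 and PPT replicate 2 both left out, counts were 2 with E2, 13 for the mean and 3 between PPT and DPN. Leaving out 1 library at a time gave 0 to 1 genes with E2, 16 to 1835 with PPT, 6 to 23 with DPN, 2 to 19 for the mean, 18 to 1629 between E2 and PPT, and 0 to 1348 between PPT and DPN, and 19 to 663 genes changed by any compound. The highest value came without PPT replicate 3, except for E2 (1) and DPN (23), where it came without PPT replicate 2. The lowest came without vehicle replicate 2 for DPN (6), and without vehicle replicate 2 or 3 for the mean (2). The cause was not tested beyond the trends on length and GC content.

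Counts of lists past camera were 1 with E2, 9 with PPT and 5 with DPN. With an estimated correlation they were 0, 0 and 0, and with fry 0, 2 and 1. With fry's test for changes in either direction they were 0, 15 and 10, with estrogen receptor targets among those with PPT (adjusted p = 0.0494). With both doubted libraries left out they were 2 with E2 and 8 with DPN, and leaving out 1 library at a time gave 0 to 2 with E2.

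Whether the replicate numbers pair the libraries stayed open. Over 18 pairs with the same number, deviations from the group means correlated by −0.0157 to 0.397, and 5 pairs were above 0.1. Pairs with different numbers ranged from −0.395 (vehicle replicate 3 and PPT replicate 2) to 0.291 (vehicle replicate 1 and PPT replicate 2). With the replicate block the counts were 45 with PPT, 14 for the mean, 45 between E2 and PPT and 3 between PPT and DPN, and 2 lists passed with E2, hypoxia and glycolysis (higher, camera adjusted p = 0.0143) and mitochondrial genes (lower, 0.0322). Without the block both had adjusted p = 0.978 with an estimated correlation. Other counts of calls under the block lay within 1.5 times their value without it. The block also turned 2 log2 fold changes that had not passed, NRIP1 with E2 (0.00642) and ESR2 with PPT (−0.0466).

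Of the comparisons of single named genes with their alternatives, 3430 agreed, 211 were no longer past the threshold, 50 passed only in the alternative and 91 changed sign; those named here had not passed. With E2 they were ESR1 (log2, TPM-scaled −0.428, quality weights −0.0374, both libraries left out −0.0999), ESR2 (no filter 0.0682, TPM-scaled 0.0687, limma-trend 0.430), GPER1 (TPM-scaled 0.0632, weights 0.0228, limma-trend 0.225), ESRRA (limma-trend 0.0167), MYC (TPM-scaled 0.0270, length and GC 0.00120), NRIP1 (no filter 0.000201, 1 CPM 0.000167, TPM-scaled 0.0590, limma-trend 0.0104, length 0.00186) and STC2 (weights −0.00881, both left out −0.0467). With PPT they were ESR2 (weights −0.306, both left out −0.173), GPER1 (weights −0.0421, both left out −0.0636), ESRRA (both left out −0.0226), NR3C1 (length and GC 0.0339, length 0.0625), NRIP1 (TPM-scaled 0.0466, length and GC 0.0235, length 0.0707) and SIAH2 (weights −0.000679). With DPN they were ESR1 (limma-trend 0.255), ESRRA (no filter 0.00177, limma-trend 0.0298, mitochondrial genes outside 0.00814), NR3C1 (TPM-scaled 0.107, length and GC 0.0120), CTSD (length and GC −0.0224, GC −0.0235), NRIP1 (TPM-scaled 0.0514, length and GC 0.0112, GC 0.00995) and IGFBP4 (length and GC −0.00564, GC −0.00698).

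Leaving out 1 library at a time gave these ranges of log2 fold change for panel genes whose sign changed. With E2 they were ESR1 −0.100 to 0.316, ESR2 −0.461 to 0.875, GPER1 −0.167 to 0.225, ESRRA −0.0509 to 0.0695, NR3C1 −0.0574 to 0.0150, MYC −0.0177 to 0.0125, CTSD −0.0499 to 0.0129, NRIP1 −0.0280 to 0.0257 and STC2 −0.0467 to 0.0603. With PPT they were ESR2 −0.314 to 1.02, GPER1 −0.111 to 0.283, ESRRA −0.00255 to 0.118, NR3C1 −0.0690 to 0.0139 and NRIP1 −0.0509 to 0.00447. With DPN they were ESR1 −0.226 to 0.190, ESRRA −0.0518 to 0.0838, NR3C1 −0.0597 to 0.0133, CTSD −0.0141 to 0.0661, NRIP1 −0.0554 to 0.0310 and IGFBP4 −0.00550 to 0.0828.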

Other observations

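The test of shared sequence among leading genes and the counts over other splits were chosen before their results were seen; the test of the number of genes with most words shared was chosen only after the result was seen, as were the settings that remove length and GC trends or leave out both doubted libraries.

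In the main analysis, camera called none of the following growth and hormone lists in the comparisons with vehicle (medians in log2 for E2, PPT and DPN, in this order). Of cell cycle genes, those of G1/S had 0.00, −0.01 and −0.02 and those of G2/M −0.02, 0.03 and −0.03. Ribosome biogenesis genes had −0.00, −0.04 and −0.03, and passed with PPT after length and GC trends were removed (lower, adjusted p = 0.0237) and with DPN when both doubted libraries were left out (lower, adjusted p = 0.0455). In the main analysis this list had adjusted p = 0.359 with PPT and 0.247 with DPN with an estimated correlation. Medians were, for MAPK output genes, 0.02, −0.03 and 0.04, Wnt targets −0.01, −0.07 and −0.03, and p53 targets 0.01, 0.08 and 0.01. Steroid-linked lists had these medians: glucocorticoid receptor targets 0.03, 0.03 and 0.06, steroid and related nuclear receptors −0.04, −0.04 and −0.01, estrogen receptor coregulators 0.00, −0.10 and −0.01, estrogen and steroid metabolism 0.01, 0.06 and 0.01, and aryl hydrocarbon receptor targets 0.01, −0.05 and 0.01. Coregulators were lower for 17 of 21 members with PPT (camera adjusted p = 0.148), and by camera at its preset correlation they differed between PPT and each of the other compounds (adjusted p = 0.588 against E2 and 0.770 against DPN with an estimated correlation).

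The metabolic and stress lists given here did not pass in the main analysis either. Cholesterol genes had medians of −0.01, 0.05 and 0.02 with E2, PPT and DPN, fatty acid synthesis 0.01, −0.07 and 0.03, the unfolded protein response 0.02, −0.04 and 0.01, heat shock genes −0.01, −0.03 and −0.02, NRF2 targets 0.00, 0.07 and 0.03, apoptosis regulators 0.01, 0.02 and 0.03, and interferon-stimulated genes 0.03, 0.03 and 0.00. With PPT, cholesterol genes (higher, adjusted p = 0.0337) and heat shock genes (lower, adjusted p = 0.0237) passed after length and GC trends were removed. In the main analysis they had adjusted p = 0.511 and 0.618 with an estimated correlation. Epithelial genes had −0.01, −0.05 and 0.02, and TGF-beta and mesenchymal genes −0.03, −0.06 and −0.01.

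Markers of other cells were summed per group. Summed CPM with vehicle, E2, PPT and DPN were 397, 420, 422 and 406 for markers of estrogen receptor-positive breast lines (medians 0.11, 0.18 and −0.01) and 1697, 1678, 1654 and 1834 for prostate basal cells (−0.06, −0.07 and −0.00), which passed camera as lower with E2 when both doubted libraries were left out (adjusted p = 0.0447, and in the main analysis adjusted p = 0.978 with an estimated correlation). The lists with fewer than 5 tested genes were not tested: fibroblast markers (13.03, 12.78, 12.73 and 13.38; COL1A1, COL3A1 and PDGFRA), leukocyte markers (41.6, 41.4, 41.6 and 42.0; LYZ and CD68), endothelial markers (36.6, 38.8, 41.7 and 39.3; KDR and PECAM1) and neuroendocrine markers (77.4, 82.4, 87.9 and 94.8; SYP and ENO2). The rise of the neuroendocrine sum was mostly that of ENO2, at 75.05 ± 4.76, 80.1 ± 3.95, 85.5 ± 4.93 and 92.5 ± 8.46 CPM (log2 0.28 with DPN, adjusted p = 0.402, limma-voom).

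Genes leading the contrast of all compounds with vehicle were expected to share more sequence with other genes than usual. This did not hold for the median: the 16 genes at an unadjusted p under 0.001 outside the mitochondrial set shared a median of 1.95% of their 31-base words, at percentile 45.9 among random sets of like expression (median 2.10%). A median cannot show what holds for part of a set, and 5 of the 16 shared over 50% of their words, against 6.06% of all genes and a median of 1 gene in the random sets (percentile 98.95). Shared reads are therefore a candidate explanation for these 5 genes, HIST2H4A, HIST2H4B, SLX1A, AP003419.1 and H3F3AP4, and are argued against for the set as a whole.

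Other splits of the libraries were counted for each comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 0 genes for E2 and the highest other 0 (10 of 10 splits as high), 20 for DPN (highest other 1; 1 of 10), 20 for E2 against PPT (highest other 1; 1 of 10), 20 for E2 against DPN (highest other 0; 1 of 10) and 0 for PPT against DPN (highest other 1; 10 of 10). For PPT the real split called 22 genes and 1 other called 2520, that of vehicle replicate 1 with PPT replicates 1 and 2 (2 of 10 as high). This points to structure among the samples that the group labels do not describe. Deviations of these 3 libraries correlated with transcript length by −0.148, −0.379 and −0.570. For vehicle replicates 2 and 3 and PPT replicate 3 the values were 0.191, 0.408 and 0.326. The split thus went with the sign of the trend on transcript length. Whether that trend accounts for the 2520 calls was not tested, and its cause was not settled. Of 100 splits of all libraries, the real one included, 2 gave as many genes for any compound (24, highest other 723). For the mean of the compounds 3 did (4, highest other 2542). Both shares lay under 0.05, without adjustment over the comparisons. The splits exchange libraries, which may be technical replicates, so chance between cultures is not excluded. The high values of single splits again point to structure among the samples.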
